A study of Caenorhabditis elegans with 2 samples.

How the data were processed

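ChIP-seq of eGFP-tagged LIN-39 was analysed in 2 biological replicates of whole, mixed-sex L3 larvae of *C. elegans*, numbered 1 and 2 as the labels number them. Per the labels, both libraries were made from fragments of 150 to 350 bp. The values used are peak lists deposited by the authors: a relaxed list for each replicate, a relaxed list of both replicates pooled, and an optimal list thresholded for reproducibility between replicates (irreproducible discovery rate, IDR). Per the labels, the files are given on the builds ce11 and ce10. Per the text indexes deposited with the samples, each list was made from alignments of its replicate or of both, and both replicates were set against the same control alignments, so that the replicates' lists are not fully independent. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here. The control's own data were not used here.

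The signal value of each peak is the authors' peak caller's signal as deposited, relative to the control and on a scale that differs between lists. It was used only to rank and describe peaks within a list. The −log10 q-value that the authors deposited for each peak sits at a ceiling of 3.95 for all 4250 optimal peaks on ce11 and was not used to rank. The deposited summit offset, in base pairs from the peak's start, gave each summit's position. A check of the lists showed that the optimal list equals the 4250 peaks of highest signal in the pooled list of 30000 (4232 on ce10). Peak widths are nearly constant within a list (median 316 bp pooled, 280 bp in replicate 1 and 344 bp in replicate 2), so widths say little about the extent of binding. Read numbers are not in these files: depth is unknown, and intervals on shares are 95% Wilson intervals that cover the counting of peaks only. With a single group of 2 samples no test between conditions was made, and no p-value measures variation between animals; tests compare positions in the genome, and the main results are also given in each replicate's own 4250 strongest peaks.

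Coordinates are 1-based on ce11, whose chromosome lengths and names fit the reference sequence used; genes and transcripts are from Ensembl release 115 for the same assembly (19973 protein-coding genes on the 6 nuclear chromosomes). Each summit was put in 1 class in the order promoter (1000 bp upstream to 200 bp downstream of a protein-coding transcript start), 5′ UTR, 3′ UTR, coding exon, intron, other exon and intergenic. Shares were tested against 1000 circular shifts of all summits along their chromosomes, two-sided, which keep the spacing of summits but not their place relative to genes. The X share was tested with an exact binomial test against its share of sequence. For gene lists, a gene was bound where an optimal summit lay in its body or 2000 bp upstream. The number bound in each of 33 lists was compared with 10000 random lists of protein-coding genes matched on decile of window length, two-sided, with Benjamini-Hochberg adjustment over lists and a threshold of 0.05. The 18 lists of named genes and 15 families by gene name, the tests and the rule for naming genes were fixed before the data were examined; 2 list entries had no gene of that name in the annotation. On simulated lists of 30 genes drawn from the 19973, the test called 3.0% of 200 unchanged lists at an unadjusted p of 0.05 and 89.5% of 200 lists whose odds of being bound were raised 4-fold. In this simulation each gene was bound or not independently of its neighbours. The rates therefore do not carry over to lists whose genes lie side by side or share peaks. Nor do they give the power for lists of other sizes.

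Named are every bound member of the lists of Hox genes and cofactors, of vulval fates and morphogenesis and of genes tied to LIN-39 in earlier work; the gene with the nearest protein-coding transcript start to each of the 15 strongest optimal peaks; the 5 genes with the most summits; for every other list past the threshold up to 4 bound members with the highest signal, and for lists not past it up to 2; *unc-119*; and the 3 strongest noncoding RNA genes of each class past the threshold. A peak's signal stands beside a gene for the strongest optimal summit in its window, and a peak between 2 genes can count for both.

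Motifs were searched on both strands within 50 bp of each summit and in a window of the same length centred 500 bp to a side drawn at random, and compared by exact McNemar tests on the peaks where only 1 of the windows held the motif. The 850 strongest and weakest peaks, and peaks of a single replicate against shared ones, were compared by permutation tests with 100000 resamples. Noncoding RNA genes within 200 bp of a summit were counted and compared with 1000 shifts. The alternatives were the 1000 strongest optimal peaks, each replicate's own strongest peaks in place of the optimal list, other rules of overlap, the files on ce10, another promoter range, peak midpoints, other gene windows, an unmatched Fisher's exact test, wider motif windows and farther flanks. Chosen after seeing the data were the opposite flank, the tests against the control strings, the optimal peaks found in both replicates' strongest lists, the alternatives for noncoding RNA genes, the rank correlation over all matched peaks of replicate 1 and the GAGAGA share by strength. The side of each flank was drawn once with a fixed seed. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Signal tracks and reads were not used here.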

Results

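LIN-39 is the Hox transcription factor of the midbody of *Caenorhabditis elegans*, best known for keeping the vulval precursor cells competent and for directing migrating neuroblasts. Its binding to DNA was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole larvae of the L3 stage, of both sexes, from strain OP18. This strain carries an eGFP-tagged copy of *lin-39* as an integrated transgene in an *unc-119(ed3)* background, and the tag was the target of the precipitation. The 2 samples are biological replicates of a single group (eGFP-LIN-39 L3), so the design implies no contrast between conditions, and the questions are where the protein was found and how far the replicates gave the same places. The list of reproducible peaks made by the authors from both replicates, called optimal here, held 4250 peaks with a median width of 316 bp on the ce11 build. Their signal ran from 33.1 to 542 with a median of 52.6. Replicate 1's own relaxed list held 30000 peaks and replicate 2's held 27572. The files give no read counts, so the depth of each library is unknown, and each peak's signal is the authors' value with no error of its own.

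Of the 15 strongest LIN-39 peaks, 10 lay in promoters and 5 in introns or intergenic sequence, 2557 to 6013 bp from the nearest start. The strongest of all (signal 542, chromosome II, 8329014 to 8329245) was 248 bp upstream of a transcript start of *hel-1*, an RNA helicase gene, and ranked 3 in replicate 1 and 1 in replicate 2. The next (signal 493, chromosome I, 1835502 to 1835716) was 63 bp upstream of *egl-30*, which encodes the Gq protein alpha subunit that acts in neurons and egg-laying muscle. The Tubby-related gene *tub-2* (signal 366, 39 bp upstream), *tasp-1* (358, 42 bp upstream), *Y77E11A.7* (352, 478 bp upstream), *cdk-7* (338, 28 bp upstream), the ribosomal protein gene *rpl-3* (324, 270 bp upstream) and *C18B12.4* (309, 339 bp upstream) came next. The remaining peaks of the 15 strongest were nearest to *K02D3.1*, *F37F2.2*, *pcyt-2.1*, *pqn-41*, *C30E1.4*, *cest-16* and *F22H10.2*, and those at *F37F2.2* and *pcyt-2.1* also lay within 200 bp of a snoRNA gene. Of the 15, only the peak nearest to *pqn-41*, which lay in an intron, had the composite Hox-cofactor motif described below within 50 bp of its summit. The ranks of these peaks differed between replicates: the *rpl-3* peak ranked 120 in replicate 1 and 2 in replicate 2, and the *C18B12.4* peak ranked 4 and 304. The peak nearest to *cest-16*, which lay inside *mom-1* and is the one counted for that gene below, ranked 417 and 5.

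Several long genes held clusters of LIN-39 summits. *mbl-1*, which encodes a muscleblind splicing factor, had 12 summits in its body and the 2000 bp upstream, more than any other gene. The heterochronic gene *lin-14* and the nucleolar size regulator *ncl-1* had 10 each, and *daf-5* and *ppfr-1* had 9 each. In these genes the strongest peak was in an intron, for example at 11471986 to 11472301 of chromosome X in *lin-14* (signal 111, rank 483 in replicate 1 and 247 in replicate 2).

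Summits were concentrated at promoters and nearly missing from coding sequence. Of the 4250 summits, 2181 (51.3%) lay from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start, against 25.6% ± 0.70 (SD over 1000 circular shifts of all summits along their chromosomes; two-sided permutation p = 0.0020, the smallest these shifts can give). The share was 48.3% in replicate 1's own 4250 strongest peaks and 50.5% in replicate 2's. Coding exons held 1.46% of summits against 18.5% ± 0.65 for shifted summits, introns 18.9% against 27.8% ± 0.79, and 3′ UTRs 0.33% against 2.63% ± 0.25 (permutation p = 0.0020 each, 0.0028 after Benjamini-Hochberg adjustment over 7 classes). Exons of genes that do not code for protein, outside the classes above, held 187 summits, 2.10-fold the shifted share (adjusted permutation p = 0.0028). Intergenic sequence, at 23.2% against 22.9% ± 0.70, and 5′ UTRs, at 0.38% against 0.42% ± 0.10, did not differ from shifted summits (adjusted permutation p = 0.775 for both). The replicates differed most in coding exons, which held 7.01% of replicate 1's own strongest summits and 1.46% of replicate 2's.

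Chromosome X carried more LIN-39 summits, and chromosomes IV and V fewer, than their lengths would give. X held 971 summits, 22.8% of the total (95% Wilson interval 21.6 to 24.1%), with 17.7% of the nuclear sequence (exact binomial test, two-sided, p = 1.29e-17). The X share was 22.4% in replicate 1's own strongest peaks and 22.5% in replicate 2's. That is 54.8 summits per Mb on X, against 51.5 on chromosome I, 50.6 on III, 41.4 on II, 34.2 on IV and 27.5 on V. Per 100 protein-coding genes, X had 35.6 summits, and chromosome V, where many chemoreceptor genes lie, had 11.5. Chromosome I was also over its share (exact binomial p = 9.70e-09) and chromosome III too (p = 7.47e-07), IV was under it (p = 3.07e-09) and V was under it (p = 3.65e-35), while II, at 14.9% of summits and 15.2% of sequence, did not differ (exact binomial p = 0.522). All of these but chromosome II held after adjustment over 6 chromosomes. The binomial test takes summits as independent, whereas some clustered in single genes, so these p-values may be too small.

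Among Hox genes and the genes of Hox cofactors, summits were found at *unc-62*, *ceh-20* and *mab-5*, and none was listed at *lin-39* itself. A gene was called bound where an optimal summit lay in its body or within 2000 bp upstream, which took in 3842 of 19973 protein-coding genes (19.2%). In the Hox list, 3 of 11 members were bound, against 3.11 expected for genes with windows of like length (95% range 1 to 6; adjusted permutation p = 1). *unc-62*, which encodes the Meis-type cofactor, had 4 summits. Its strongest peak (chromosome V, 4507860 to 4508080, signal 173) lay in a 5′ UTR and ranked 246 in replicate 1 and 47 in replicate 2. A composite motif, TGATGGAT, lay 3 bp from that summit, at 4508004 to 4508011, in the sequence GCCTTGGCAATGATGGATCGCCGCAGCT. *ceh-20*, which encodes the Pbx-type cofactor with which LIN-39 binds DNA, had 1 summit 745 bp upstream of its start (chromosome III, 6978981 to 6979296, signal 100.3). The neighbouring Hox gene *mab-5* had 2 summits, the stronger 1015 bp upstream (chromosome III, 7784311 to 7784626, signal 43.1). The *lin-39* gene (chromosome III, 7528641 to 7536632, minus strand) held no summit in its window in the optimal list, in the pooled relaxed list or in either replicate's relaxed list. The stretch without a summit around it ran from 7520856 to 7556673 in the pooled list, 35817 bp, and 0.50% of the gaps between neighbouring summits of that list were as long. The nearest optimal summit, in the shared promoter region of *cux-7* and *C07H6.2* at 7520698 to 7521013, lay 7785 bp from the gene with a signal of 106. The bounds and copy number of the transgene are not given in the sources used here, and extra copies in the precipitated or control sample would alter the calls at this locus, so the missing peaks do not show a lack of binding. *ceh-13*, *egl-5*, *php-3*, *nob-1*, *ceh-40*, *ceh-60* and *psa-3* were not bound in the optimal list. Unlike *lin-39*, some of them had weaker summits in their windows in the pooled relaxed list: 3 at *nob-1* and 1 each at *ceh-13*, *ceh-60*, *php-3* and *psa-3*. An optimal summit of signal 42.9 lay 2000 bp beyond the end of *ceh-13*.

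**Figure D1:**
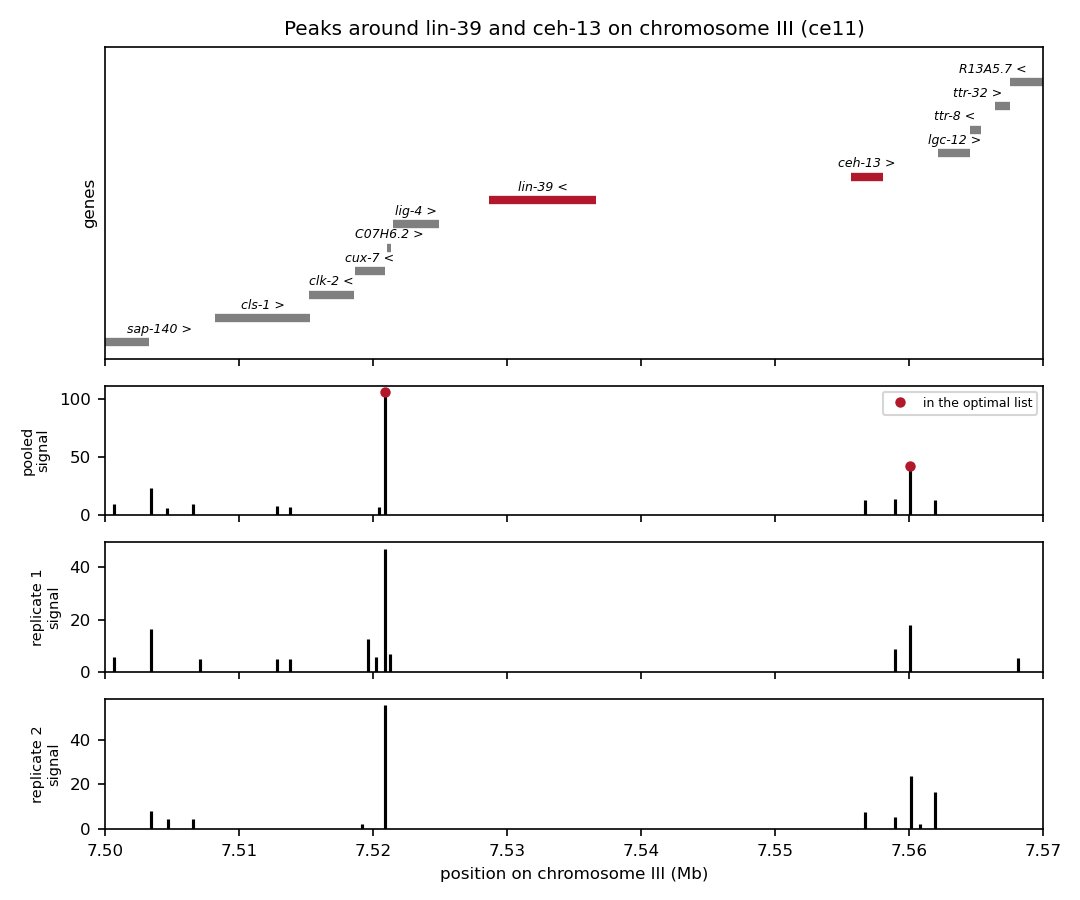
Genes (top; arrowheads give the strand) and peak summits on chromosome III around *lin-39*, with vertical lines for each summit's signal in the pooled list, replicate 1 and replicate 2, and red points for summits of the optimal list. No list has a summit inside *lin-39* or in the 2000 bp upstream of it, and the peak of signal 106 beyond *lig-4* is present in both replicates.

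Genes of vulval development and genes tied to LIN-39 in earlier work were not bound more or less often than matched genes past the threshold. Of the 16 genes with such ties, 6 were bound against 4.33 expected (95% range 1 to 8; adjusted permutation p = 0.581). These were the cell cycle genes *cye-1* (555 bp upstream, signal 138) and *cdk-4* (435 bp upstream, 90.6), the GATA factor gene *egl-18* (intron, 94.0), the neuroblast migration gene *mig-13* (302 bp upstream, 59.7), *mab-5*, and the Notch receptor gene *lin-12* (intron, 35.4, with a motif TGATAGAT 46 bp from the summit). The *mig-13* peak ranked 1017 in replicate 2 but 6839 in replicate 1, outside its 4250 strongest, and the *lin-12* peak ranked 1932 in replicate 1 but 5637 in replicate 2. At optimal peaks found in both replicates' own strongest lists, 4 of these 16 genes were bound. Among 25 genes of vulval fates and morphogenesis, 4 were bound against 7.2 expected (95% range 3 to 12; adjusted permutation p = 0.327), with 6 in replicate 1's own peaks and 2 in replicate 2's (adjusted permutation p = 1 and 0.0540; range over alternatives 0.0540 to 1). Besides *egl-18* they were the FGF gene *egl-17* (246 bp inside the gene, signal 62.4), *hlh-2* (1133 bp upstream, 42.6) and *let-413* (1357 bp upstream, 33.5). The last 2 ranked 15989 and 13932 in replicate 2. *lin-11*, *lin-29*, *nhr-67*, *cog-1*, *eff-1* and *ref-2* held no optimal summit in their windows. Weaker peaks of the pooled list are not given for these genes, and whole larvae do not separate cell types. The missing optimal summits therefore do not show a lack of binding. Of 30 genes of vulval induction by EGF-Ras and Notch signalling, 12 were bound against 9.34 expected (adjusted permutation p = 0.485), led by *dpy-23* (signal 173) and the MAP kinase gene *mpk-1* (131). None of these vulval and LIN-39 lists passed in either replicate's own peaks, and vulval induction passed, of 8 alternatives, only under Fisher's exact test without matching (adjusted p = 0.0165; range over alternatives 0.0165 to 1).

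LIN-39 summits were far more frequent at genes of the translation and protein degradation machinery and at pan-neuronal genes than at matched genes. Of 33 lists, 7 held more bound genes than 10000 matched random lists gave. Of 78 ribosomal protein genes, 72 were bound against 10.5 expected (95% range 5 to 17; two-sided permutation p = 0.00020, the smallest the lists can give; adjusted p = 0.000825), with 68 bound in replicate 1's own strongest peaks and 71 in replicate 2's. The strongest were at *rpl-3* (signal 324), *rps-28* (249), *rpl-12* (241) and *rps-12* (236), each within 429 bp upstream of the gene start. Where each summit counted only for the nearest gene start, 40 of the 78 were bound (8.38 expected, adjusted permutation p = 0.00110). Of 33 proteasome genes, 20 were bound against 4.85 expected (95% range 1 to 9; adjusted permutation p = 0.000825), with 14 and 20 bound in the own peaks of replicates 1 and 2, among them *rpn-3* (signal 120.1), *rpt-6* (109), *pas-4* (103) and *pbs-1* (89.1). By the nearest gene start, 13 proteasome genes were bound (3.99 expected, adjusted permutation p = 0.00110). Of 25 pan-neuronal genes, 21 were bound against 7.2 expected (95% range 3 to 12; adjusted permutation p = 0.000825), and 21 in each replicate's own list. They were led by the tubulin genes *tba-1* (signal 248) and *tbb-1* (128), the active-zone gene *syd-2* (138) and the synaptic vesicle gene *rab-3* (124). The *rab-3* peak, in a promoter-class position inside the gene (chromosome II, 5725151 to 5725466), had a motif TGATGTAT 3 bp from its summit. *unc-119*, the marker gene of the strain and a member of this list, had 2 summits, the stronger in an intron with a signal of 53.2.

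Genes of cell migration, muscle, the cell cycle and developmental timing were also bound more often, but each of these calls was lost under some alternatives. In cell migration and axon guidance, 23 of 35 genes were bound against 13 expected (95% range 8 to 19; adjusted permutation p = 0.00264), with the strongest peaks at *unc-76* (signal 141, motif TGATTGAT 8 bp from the summit), the netrin receptor gene *unc-40* (141), the semaphorin gene *mab-20* (119.7) and the Robo gene *sax-3* (119.6, motif TGATAAAT). In body wall muscle, 17 of 28 were bound against 7.97 expected (95% range 4 to 13; adjusted permutation p = 0.000825), including *act-4* (signal 137), *unc-97* (83.6), *pat-2* (73.9, rank 4304 in replicate 1) and the twitchin gene *unc-22* (63.8). Body wall muscle turned among the 1000 strongest peaks, with 2 bound genes, 0.86 of the expected number. In replicate 1's own peaks alone neither list passed, with 20 and 14 bound genes and adjusted permutation p = 0.0711 and 0.0627, while over all alternatives the adjusted p ran from 1.32e-08 to 0.422 and from 6.52e-06 to 1. A window of 1000 bp upstream to 500 bp downstream of the gene start is equally long for every gene. With it, 7 cell migration genes were bound (4.36 expected, adjusted permutation p = 0.422) and 10 muscle genes (3.47 expected, adjusted permutation p = 0.00924). Of 29 cell cycle genes, 13 were bound against 6.52 expected (95% range 3 to 11; adjusted permutation p = 0.0354), led by *mcm-4* (signal 165), *cye-1* (138), *efl-1* (114) and *cdk-4* (90.6). The cell cycle call ended with 5000 bp upstream (adjusted permutation p = 0.123) and with the nearest gene start to each summit (0.0655; range over alternatives 0.000943 to 0.123). Of 16 heterochronic genes, 10 were bound against 5.18 expected (95% range 2 to 9; adjusted permutation p = 0.0475), led by *lin-66* (170), *lin-14* (111), *lin-42* (103.0) and *lin-41* (99.1). The heterochronic call ended in replicate 2's own peaks, with 9 bound genes and adjusted permutation p = 0.104, and with 5000 bp upstream (0.0883; range over alternatives 0.000525 to 0.104).

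**Figure D2:**
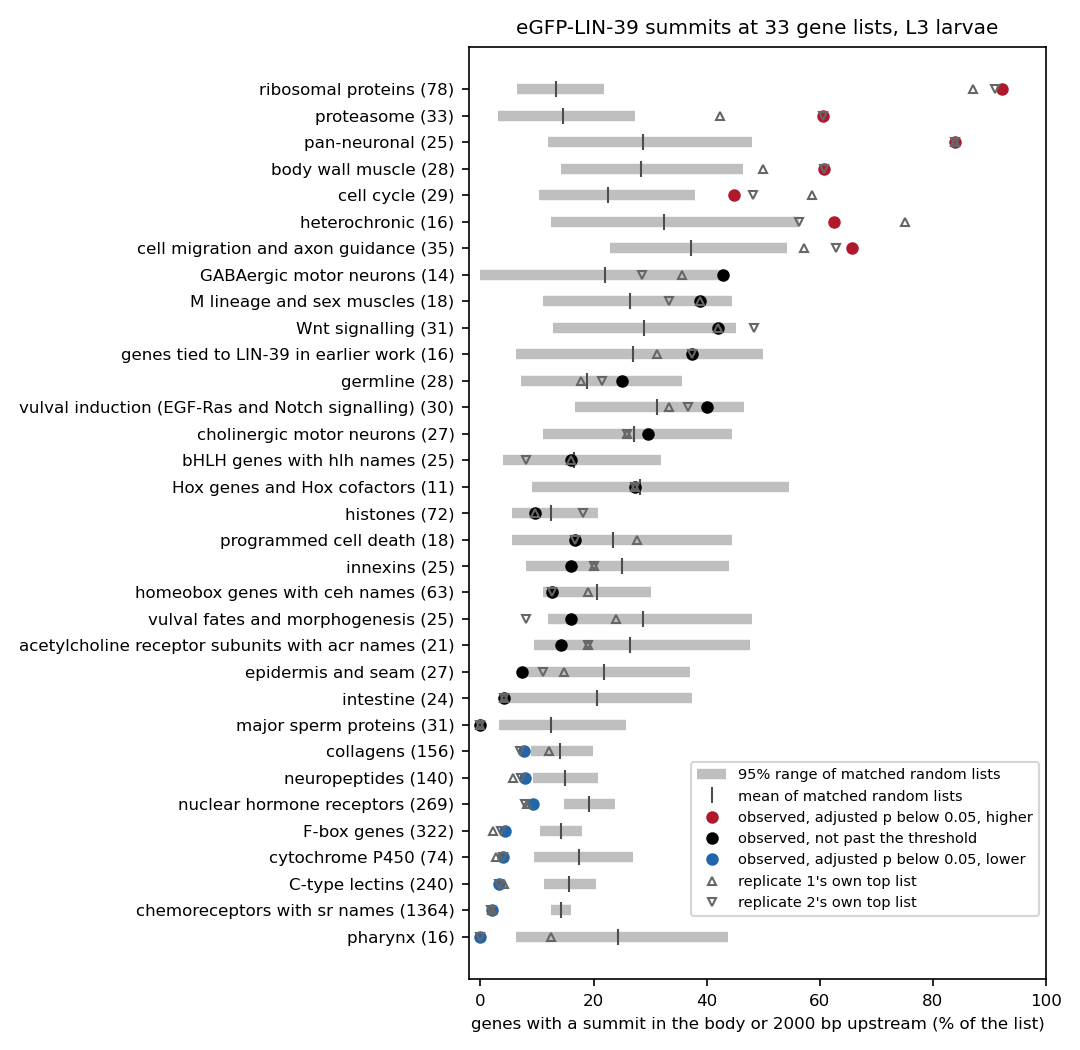
Share of each gene list with an optimal summit in the gene body or 2000 bp upstream (points; list size in brackets), with the mean and 95% range of 10000 random lists matched on window length and the shares in each replicate's own 4250 strongest peaks (triangles). Ribosomal protein genes (72 of 78) and pan-neuronal genes (21 of 25) lie far above the range in both replicates, and chemoreceptor genes (29 of 1364) far below it.

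Large families of sensory, defence and detoxification genes were bound less often than genes matched on window length. Chromosome and position were not matched, and summits were unevenly spread, with 27.5 per Mb on chromosome V and 54.8 on X. Location was thus not separated from gene family. The test also draws genes as independent, so p-values may be too small where members of a family lie side by side. Chemoreceptors with *sr* names, which act mostly in sensory neurons, had 29 of 1364 bound against 195 expected (95% range 171 to 219; adjusted permutation p = 0.000825). The few strongest were at *srh-2* (signal 106), *sri-5* (87.3), *srbc-58* (87.3) and *srr-10* (85.7), of which the *srh-2* peak ranked 14753 in replicate 1. C-type lectins had 8 of 240 against 37.8 expected (adjusted permutation p = 0.000825), led by *clec-140* (105), *clec-113* (78.2), *clec-126* (75.7) and *clec-91* (66.6). F-box genes had 14 of 322 against 45.9 (adjusted permutation p = 0.000825), with 7 in replicate 1's own peaks and 12 in replicate 2's, led by *fbxb-58* (139), *fbxa-90* (114), *fbxb-85* (95.4) and *fbxa-128* (55.5). The *fbxa-90* peak was the same as that named for *efl-1*, 971 bp upstream of *fbxa-90* and 168 bp upstream of *efl-1*. Nuclear hormone receptors had 25 of 269 against 51.5 (adjusted permutation p = 0.000825), led by *nhr-48* (162), *nhr-47* (116), *nhr-3* (114) and *nhr-1* (112.6). Cytochrome P450 genes had 3 of 74 against 12.9 (adjusted permutation p = 0.00147): *cyp-37A1* (51.98), *cyp-33C8* (38.7), whose peak was in neither replicate's 4250 strongest (ranks 4662 and 4808), and *cyp-35A2* (33.6), ranked 15416 in replicate 1. The nuclear hormone receptor, P450 and neuropeptide calls ended among the 1000 strongest peaks, and the neuropeptide call also with the nearest gene start to each summit. Neuropeptide genes had 11 of 140 against 20.9 (adjusted permutation p = 0.0475), led by *ins-39* (149), *nlp-12* (137), *nlp-45* (59.7) and *nlp-76* (56.4). Collagens had 12 of 156 against 22.0 (adjusted permutation p = 0.0475), led by *col-38* (119.4), *col-94* (112.8), *col-99* (95.8) and *col-8* (84.2), but replicate 1's own peaks bound 19 (adjusted permutation p = 1; range over alternatives 0.000292 to 1). Of 16 pharynx genes 0 were bound against 3.90 expected (adjusted permutation p = 0.0475), and this call was lost under each of 8 alternatives, with 2 bound genes in replicate 1's own list (adjusted permutation p = 0.757; range 0.0528 to 0.854).

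The other lists did not pass the threshold with the optimal list and matched random lists. Wnt signalling had 13 of 31 bound (8.94 expected; strongest *mom-1*, 266, and *mig-5*, 142), cholinergic motor neurons 8 of 27 (7.35; *unc-37*, 119.7, and *dbl-1*, 74.3) and GABAergic motor neurons 6 of 14 (3.07; *unc-25*, 57.2, and *snf-11*, 52.4). The M lineage and sex muscles had 7 of 18 (4.77; *unc-62* and *sma-9*, 103.0, absent from replicate 1's list), the germline 7 of 28 (5.29; *nos-3*, 112.8, and *cgh-1*, 96.97) and programmed cell death 3 of 18 (4.21; *ced-2*, 76.6, and *ced-9*, 70.3). Epidermis and seam had 2 of 27 (5.88; *egl-18* and *ajm-1*, 66.8), and the intestine 1 of 24 (4.96; *pgp-1*, 59.1). Histones had 7 of 72 (9.05; *his-35* and *his-37*, which share a peak of signal 151 that ranked 4253 in replicate 1), major sperm proteins 0 of 31 (3.85), homeobox genes with *ceh* names 8 of 63 (13; *ceh-38*, 215, and *ceh-5*, 120.7) and bHLH genes with *hlh* names 4 of 25 (4.14; *hlh-11*, 119.9, and *hlh-30*, 109, rank 4326 in replicate 2). Acetylcholine receptor subunits with *acr* names had 3 of 21 (5.57; *acr-12*, 49.6, and *acr-9*, 42.1, rank 5526 in replicate 2) and innexins 4 of 25 (6.27; *inx-7*, 157, and *inx-11*, 68.0). Leaving out a replicate turned the direction of 5 of these lists or moved 2 others by over 1.5-fold, none past the threshold: in replicate 2's own peaks 13 histone genes were bound (1.41-fold the expected number), 7 cholinergic (0.98), 3 epidermal (0.52) and 2 *hlh* genes (0.49), and in replicate 1's 7 cholinergic (0.96), 5 germline (0.99), 5 cell death (1.22), 4 epidermal (0.70), 12 *ceh* (0.97) and 4 *hlh* genes (1.04). For these lists the adjusted permutation p ran from 0.0656, for major sperm proteins, to 1. Some passed under an alternative: Wnt signalling with Fisher's exact test (adjusted p = 0.00903) and with 5000 bp upstream (0.0110; range over alternatives 0.00903 to 0.480), major sperm proteins, still with 0 bound, under the same alternatives (exact 0.00487 and permutation 0.00960; range 0.00487 to 0.809), and the intestine with the nearest gene start to each summit (adjusted permutation p = 0.0473; range 0.0473 to 0.809).

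Genes of short noncoding RNAs lay next to many LIN-39 summits. Within 200 bp of a summit were 183 of 612 tRNA genes against 13.5 ± 3.95 (SD over 1000 shifts), 90 of 346 snoRNA genes against 8.04 ± 2.9 and 15 snRNA genes against 2.53 ± 1.66 (two-sided permutation p = 0.0020 each, 0.0027 adjusted over 4 classes). In the replicates' own lists the numbers were 180 and 148 for tRNA, 87 and 87 for snoRNA, and 16 and 16 for snRNA genes, in replicates 1 and 2. The strongest snoRNA peaks were at *F37F2.4* (signal 287), *Y37E3.20* (287) and *ZK20.9* (201). The strongest snRNA peaks were at the splice leader genes *sls-2.1* (198) and *sls-2.4* (185) and at *T11F9.15* (155), and the strongest tRNA peaks were at the genes WBGene00023055 (216), WBGene00023042 (111.6) and WBGene00014333 (109), each in an intron. Of 261 miRNA genes, 10 lay near a summit against 5.80 ± 2.66, which did not pass (permutation p = 0.196), whereas replicate 1's own peaks gave 15, 2.60-fold the shifted number (permutation p = 0.00599), and the 1000 strongest gave 3.67-fold (permutation p = 0.0420).

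The composite Hox-cofactor motif was slightly more frequent at summits than beside them, and against flanks this held in replicate 2's own peaks and not in replicate 1's. LIN-39 binds DNA together with CEH-20 at sites of the form TGATNNAT. This motif lay within 50 bp of 8.92% of summits (95% Wilson interval 8.10 to 9.81%) and in 7.08% (6.35 to 7.89%) of windows 500 bp to a random side (ratio 1.26, exact McNemar test, two-sided, p = 0.00190). In replicate 2's own strongest peaks the shares were 10.3% and 7.32% (exact p = 1.65e-06), and in replicate 1's they were 6.35% and 6.73% (exact p = 0.512). The ratio was 0.985 among the 1000 strongest optimal peaks (exact p = 1), 1.04 with windows of 100 bp to each side (exact p = 0.479) and 1.12 with flanks at 1000 bp (exact p = 0.129). The reversed string TANNTAGT, a control of like base composition, was rarer at summits (1.41%) than beside them (4.09%, exact p = 1.51e-14). Set against this control, in a comparison chosen after seeing the data, the ratio for TGATNNAT was 3.65-fold that of the control (Fisher's exact test, p = 2.17e-16), 2.89-fold in replicate 1's own peaks (exact p = 2.60e-09), 3.996-fold in replicate 2's (exact p = 1.42e-19) and 2.96-fold among the 1000 strongest (exact p = 0.00292). The homeodomain core TAATTA was also rarer, at 1.15% against 4.89% (exact p = 1.04e-24), as was its rearranged control TTAAAT, at 3.20% against 17.6% (exact p = 6.05e-109), and set against this control TAATTA turned to a ratio of 1.29 (Fisher's exact p = 0.0558, also chosen after seeing the data). Summit windows had a mean GC content of 48.5% ± 6.74 (SD over 4250 peaks) and flanks 35.5% ± 8.84.

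Other strings also differed between LIN-39 summits and flanks. No composition control was run for them, and the higher GC content of summits by itself raises GC-rich strings and lowers AT-rich ones, so their ratios cannot be ranked against that of the Hox motif. GAGAGA lay at 28.2% of summits (95% interval 26.9 to 29.6%) and in 5.27% of flanks, a ratio of 5.35 (exact p = 1.80e-177), with 26.9% of summits in replicate 1 and 26.2% in replicate 2. The E2F-type string TTTGCGC was at 3.13% against 1.20% (exact p = 6.34e-10) and the E-box CACGTG at 3.04% against 1.91% (exact p = 0.00107), while the GATA string WGATAR was rarer at summits, 13.2% against 20.3% (exact p = 1.26e-18). All 8 motif tests stayed past 0.05 after Benjamini-Hochberg adjustment. Of 2080 possible strings of 6 bases, 891 were more frequent at summits and 636 less frequent at an adjusted exact p below 0.05. The highest ratios among those at 5% of summits or more were for CCCCCC (9.72), GCGCGC (9.34) and CGCGCG (8.72), and GACGCA, at 14.5% of summits, had a ratio of 6.48.

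The strongest peaks were more often at promoters and less often at the Hox motif. Among the 850 strongest and 850 weakest optimal peaks, the promoter class held 61.8% and 46% of summits (permutation p = 1.0e-05, the smallest that 100000 resamples can give). The shares with TGATNNAT were 6.47% and 9.88% (permutation p = 0.0125, 0.0150 adjusted), and those with GAGAGA were 31.4% and 26% (permutation p = 0.0153). Base composition was not matched here, and strong peaks were richer in GC. Shared peaks among the 1000 strongest of replicates 1 and 2 had 53.2% and 51.4% GC. Among the 4250 strongest, shared peaks had 50.3% and 48.7%. The lower TGATNNAT share at strong peaks may thus follow from base composition.

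**Figure D3:**
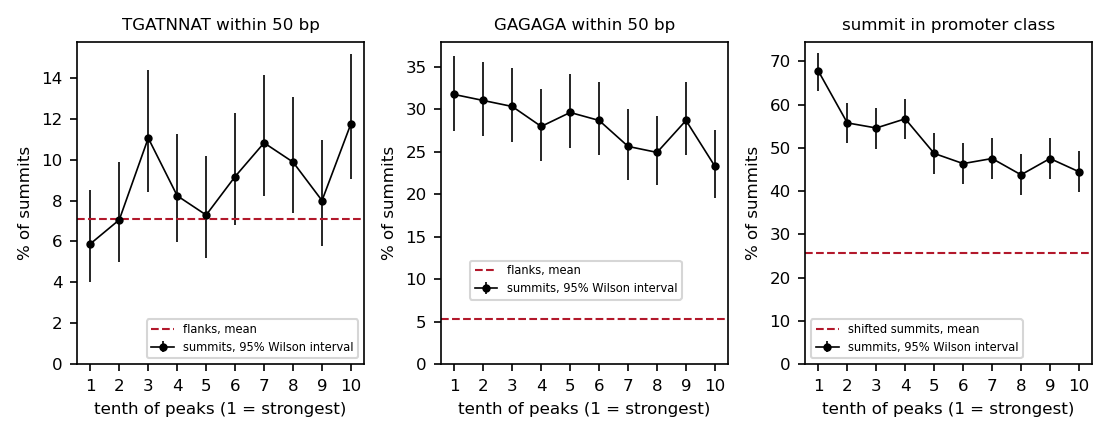
Share of summits with TGATNNAT within 50 bp, with GAGAGA within 50 bp and in the promoter class, in groups of 425 optimal peaks ordered by signal (1 = strongest), with 95% Wilson intervals and the mean of flanks or shifted summits (dashed). The promoter share fell from 67.8% to 44.5%, and the TGATNNAT share was 5.88% in the strongest 425 and 11.8% in the weakest.

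The replicates shared most of the optimal peaks but ranked them differently. Of the 4250 optimal peaks, 71.7% (95% Wilson interval 70.4 to 73.1%) held the summit of one of replicate 1's own 4250 strongest peaks, and 79.6% (78.4 to 80.8%) that of one of replicate 2's. In the full relaxed lists the shares were 94.1% and 98.0%. The optimal list equals the 4250 peaks of highest signal in the pooled list, so a place in it does not itself require a strong peak in both replicates, and 2408 optimal peaks (56.7%) overlapped a peak of both replicates' own 4250 strongest. Of replicate 1's strongest peaks 57.1% overlapped one of replicate 2's, against 2.72% ± 0.25 (SD) for replicate 2's peaks shifted along the chromosomes 100 times. Across 4053 optimal peaks found in both relaxed lists, Spearman's rho of the signal was 0.30 and Pearson's r of log2 signal 0.30; this is across peaks, which are not independent replicates. The range of signal is narrowed there by the choice of peaks: rho was 0.56 across the 11928 peaks of replicate 1's relaxed list that overlapped one of replicate 2's, and 0.02 among the 1000 strongest optimal peaks.

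**Figure D4:**
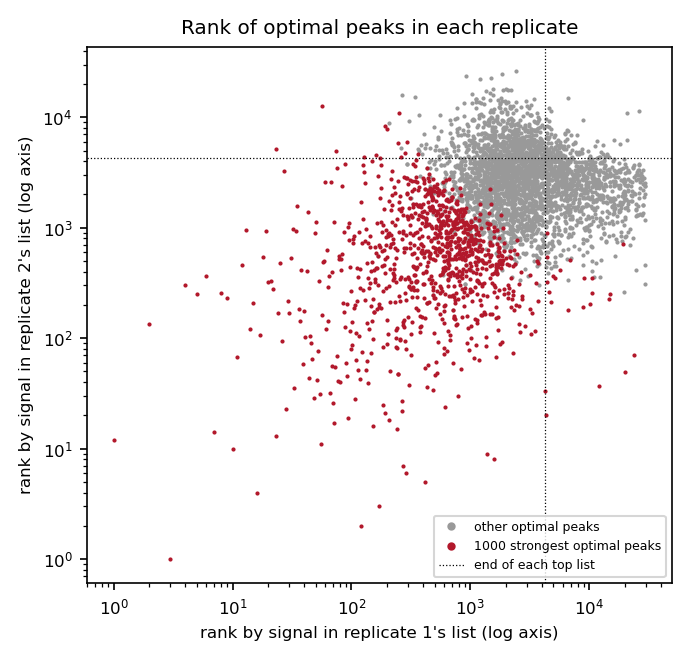
Rank by signal of each optimal peak in replicate 1's (x) and replicate 2's (y) relaxed list, on log axes, for the 4053 peaks found in both; red points are the 1000 strongest optimal peaks and dotted lines mark rank 4250. Most red points lie inside both lines, with no trend among them (rho 0.02).

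Peaks strong in a single replicate were less often at promoters, and those of replicate 2 more often held the Hox motif. In replicate 1, 1822 of the 4250 strongest peaks (42.9%) overlapped none of replicate 2's, and in replicate 2, 1807 (42.5%) overlapped none of replicate 1's. TGATNNAT lay at 13.2% of the peaks of replicate 2 alone and at 8.15% of its shared peaks (permutation p = 1.0e-05), but at 5.16% and 7.25% in replicate 1 (permutation p = 0.00585). Among the 1000 strongest peaks of each replicate, the shares were 12.5% and 6.34% in replicate 2 (permutation p = 0.00102). In replicate 1 they were 4.31% and 6.90%, which did not pass (permutation p = 0.101). Promoter shares were 40% against 54.4% in replicate 1 and 45.3% against 54.4% in replicate 2 (permutation p = 1.0e-05 each). The mean GC content of the peaks of a single replicate was 50% in replicate 1 and 42.8% in replicate 2, and that of shared peaks was 50.3% and 48.7%. Against the other replicate's full relaxed list, 493 and 582 peaks had no overlap.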

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

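The report uses the 4250 peaks of the optimal list and sets aside the weaker peaks of the pooled list, apart from the gap around *lin-39*, and the Hox motif was more frequent at some of these peaks, which no motif comparison of the report used. This test was chosen only after the result in the optimal list was seen. At pooled peaks of rank 4251 to 10000, TGATNNAT lay within 50 bp of 8.68% of summits and in 7.46% of flanks (exact McNemar test, two-sided, p = 0.0174; 0.0347 adjusted). The share is close to the 8.92% of the optimal list. The difference was not past the threshold at ranks 10001 to 20000 (7.86% against 7.15%, adjusted exact p = 0.0792) or at ranks 20001 to 30000 (7.15% against 7.68%, exact p = 0.158). Whether the difference holds in each replicate was not tested for these ranks.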

How the results depend on the processing

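The share of summits at promoters, the X share, the rarity of TAATTA against flanks and the number of over-represented lists (5 to 9) kept their direction and their side of the threshold, or stayed within 1.5-fold, under every alternative run for them but 1. Against its control string TAATTA turned, with a ratio of 1.29 (exact p = 0.0558), 0.808 among the 1000 strongest and 1.37 in replicate 1's own peaks (exact p = 0.0318), a comparison chosen after seeing the data. The motif TGATNNAT at summits was less stable: its ratio of 1.26 turned to 0.985 among the 1000 strongest optimal peaks, ranged from 0.944 to 1.41 when either replicate was left out, and lost its threshold at optimal peaks found in both replicates' strongest lists (1.22), within 100 bp (1.04) and with flanks at 1000 bp (1.12). Against the opposite flank it was 1.18 and against the control string 3.65; these 2 settings and the peaks found in both lists were chosen after seeing the data. Under-represented lists fell to 3 of 8 among the 1000 strongest peaks, where fewer bound genes leave less room below expectation, and body wall muscle turned there (0.861). The overlap with replicate 1 was 69.8% with reciprocal overlap and 76.9% for the 1000 strongest, and with replicate 2 80.8% with any overlap, 77.6% with reciprocal overlap and 72.0% for the 1000 strongest. Rank agreement was 0.0195 among the 1000 strongest and 0.558 over all matched peaks of replicate 1 (chosen after seeing the data); the first narrows the range of signal and the second widens it. Peaks of a single replicate were 46.4% in each replicate for the 1000 strongest, and 11.6% and 13.7% against the other's full list, which is longer. For the other changes the cause was not tested. Across single gene lists, 230 values kept their side of the threshold, 27 lost it, 6 gained it and 1 (body wall muscle) turned. Of 94 named genes, 67 were still bound among the 1000 strongest, 91 without replicate 1, 88 without replicate 2, 83 at peaks found in both lists and 94 with 5000 bp upstream. No paired analysis was possible because the series has 1 group. Depth limits could not be measured, since the files give no read counts.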

Other observations

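The scan of gene names, the split of TGATNNAT by its inner bases, the look at single strong peaks and the test on snRNA genes below were chosen only after the results were seen. LIN-39 summits were also counted at groups of genes formed by name alone, some of which are families of the report's lists. Of 175 groups of at least 10 protein-coding genes sharing a name, 20 held more bound genes than matched lists and 25 held fewer. Here too the lists were matched on window length and not on chromosome or position. Among those not in the report's families, bound more often were translation initiation factors named *eif* (15 of 25, 4.42 expected; adjusted permutation p = 0.00233), *rab* GTPases of vesicle traffic (14 of 20, 3.65 expected) and *vha* subunits of the proton pump (12 of 20, 3.45 expected). So were *dnj* chaperones (15 of 29, 6.09 expected), *cox* subunits of cytochrome oxidase (9 of 15, 2.97 expected), *mdt* subunits of Mediator (11 of 20, 4.08 expected), mitochondrial ribosomal *mrpl* genes (16 of 41, 7.03 expected) and *vps* sorting genes (15 of 31, 7.19 expected). Genes named *unc* for uncoordinated movement had 64 of 94 bound (30.3 expected), 64 in replicate 1's own list and 62 in replicate 2's, and share members with the neuronal, muscle and migration lists. Genes named *lin* for altered cell lineage had 25 of 47 (13.7 expected). Bound less often were *oac* acyltransferases (1 of 56, 12.3 expected), *irld* receptor-like genes (1 of 56, 9.70 expected), *ugt* transferases (3 of 67, 12.5 expected), *lgc* channels (5 of 56, 14.4 expected), *gcy* guanylyl cyclases (3 of 31, 9.79 expected) and *best* chloride channels (0 of 26, 5.37 expected).

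Among the forms of the Hox-cofactor motif, TGATTGAT and TGATGGAT passed the threshold, and no control string was run for single forms. TGATTGAT lay at 2.02% of summits and in 0.45% of flanks (ratio 4.53, exact McNemar test, adjusted p = 3.69e-10; ratio 3 in replicate 1 and 3.85 in replicate 2). TGATGGAT lay at 1.27% and 0.52% (ratio 2.45, adjusted exact p = 0.00205; 2.22 and 2.27 in replicates 1 and 2). None of the other 14 forms passed after adjustment, but TGATTAAT came close to TGATGGAT. Its ratio was 2.29 (adjusted exact p = 0.0531), with 1.11 in replicate 1 and 1.95 in replicate 2. TGATTGAT and TGATGGAT were more frequent at summits than in flanks in both replicates' own peaks. For the motif with open inner bases that comparison passed in replicate 2's own peaks alone, though against the control string its ratio was 2.89-fold higher in replicate 1's as well. Of the 1000 strongest optimal peaks, 3 overlapped no peak of replicate 1's relaxed list and 0 were missing from replicate 2's. They lay in an intron of *sma-9* (chromosome X, 10771063 to 10771378, rank 183 in replicate 2), at 16931333 to 16931648 of X (rank 176) and at 8762523 to 8762838 of chromosome IV (rank 849). The *lin-39* gene was among 431 of 19973 protein-coding genes (2.16%) that lay in gaps as long as its own in the pooled list and in both replicates' lists.

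Summits at ribosomal protein, tRNA and snoRNA genes may come from composite Hox sites, or from enrichment at strongly transcribed genes whatever the factor. Of 326 such summits 2.45% held TGATNNAT, against 9.45% of 3924 others, a difference of -7.001 percentage points (permutation p = 5.0e-05). GAGAGA was also rarer there (12.3% against 29.5%), and base composition was not matched. The lower share is thus not particular to the Hox motif, and the difference itself decides nothing about the cause. Few of these summits, however, had a composite site within 50 bp that could account for them. Enrichment at strongly transcribed genes would also appear at snRNA genes, where it was 5.93-fold, but this value was known when the test was chosen and so decides nothing. Histone genes (7 of 72, 0.77-fold) and collagens (12 of 156, 0.55-fold) were not enriched. In single replicates they varied, with 13 histone genes (1.41-fold) in replicate 2's own peaks and 19 collagens (0.97-fold) in replicate 1's. Proteasome (4.12-fold), *eif* (3.40-fold), *vha* (3.48-fold) and *cox* genes (3.03-fold) were enriched. Transcription was not measured, and no list of another factor or of the control was analysed here, so enrichment at strongly transcribed genes stays open. No biological explanation other than the composite sites was tested, because the series has 1 group.

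Replicate 2's own peaks held TGATNNAT more often than replicate 1's (13.2% against 5.16% of the peaks of a single replicate, 8.01 points), and base composition or weak peaks could be a cause. Within 5 groups of like GC content the difference was 4.38 points (permutation p = 6.0e-05), so GC content can account for part of it. In the group of highest GC content the order was the opposite (1.27% of 79 against 2.72% of 588). The groups were coarse and unequally filled, with 691 peaks of replicate 2 and 170 of replicate 1 in the lowest. GC content may still differ within them, so whether it accounts for the whole is not settled. Among the 1000 strongest peaks of each replicate the difference was 3.5 points (9.2% against 5.7%, permutation p = 0.00355), and among those found in a single replicate the shares were 12.5% and 4.31%, which argues against weak peaks as the cause. Both replicates were set against the same control alignments; depth, library and batch stay open, and no biological explanation was tested.

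Sparse outer parts of the autosomes and more promoter sequence on X were examined as explanations of the excess on chromosome X. X held 54.8 summits per Mb against 49.2 in the central 50% of the autosomes and 30.2 in the rest, a ratio of 1.11 (exact binomial p = 0.00601). Sparse outer parts can thus account for much of the excess. Whether they account for the whole is not settled, because the test takes clustered summits as independent and pools autosomes that differ. Chromosomes I and III, outer parts included, held 51.5 and 50.6 summits per Mb, and IV and V 34.2 and 27.5. X held 19.8% of promoter-class summits with 14.7% of promoter-class sequence, a ratio of 1.34 (exact binomial p = 1.60e-10). With 17.7% of the nuclear sequence, X had less promoter sequence than its length would give. Of the summits on X, 44.4% were in the promoter class, against 53.4% on the autosomes. These values argue against more promoter sequence on X as the cause. Copy number and mappability of X were not tested, and no biological explanation was tested.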
